A study of Mus musculus with 2 samples.

How the data were processed

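The labels describe ATAC-seq libraries of mouse regulatory T cells, 2 libraries of 1 group, taken in this group and with these replicate numbers from the labels. Each library had a list of accessible regions in narrowPeak form on mm10, per the labels and the deposited text files, made from the alignments of that library alone and not from pooled reads. Entry names in the deposited lists include words for masking, removal of duplicates and sorting, and the words ASTARR and insert, whose meaning is not given in the sources used here. It was thus not established whether the lists came from plain ATAC-seq libraries or from inserts made for another assay. The aligner, the peak caller, their versions and the treatment of transposase offsets are not given in the sources used here. A linked protocol for differentiating CD4 T cells was not read.

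The lists hold values that the authors gave to each region, and these were used to rank or filter regions within a list. Between the lists, ranks by signal or -log10 q were compared in the rank correlation of matched regions. The values themselves were set against each other in the weighing of the longer list of replicate 2. The deposited score stops at 1000, a value held by 10956 entries of replicate 1 and 15954 of replicate 2. It equalled 10 times the -log10 q, rounded down and limited to 1000, in every entry of replicate 1 and in all but 2 entries of replicate 2, so it was not used further. The deposited signal of each region, with a median of 6.57 in replicate 1 and 6.06 in replicate 2, has no stated scale, and what it is relative to is not given. The deposited -log10 p and -log10 q values place a limit on the lists: the lowest -log10 q was 1.00 in both. The sequencing depth is unknown, since the lists hold no counts, and no interval that needs a depth is given. Entries within a list did not overlap, so merging changed nothing.

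Coordinates were compared with the GRCm38 genome, which is the mm10 build, and with GENCODE release M21. No entry passed the end of a chromosome. Analyses used chromosomes 1 to 19, X and Y. Regions outside these numbered 71 in replicate 1 and 84 in replicate 2. Regions were called shared where they overlapped by at least 1 bp, and 20 shuffles within chromosomes that avoid gaps gave the chance share. Region midpoints were assigned in the order promoter, exon, intron and intergenic, with promoters within 1 kb of a start site of a protein-coding gene.

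Before the data were examined, 21 gene lists, 26 consensus motifs, the tests, the alternatives and the rule for named genes were fixed. The lists covered regulatory T cell core, pan T cell, T helper 1, T helper 2, T helper 17, follicular helper T, naive and quiescent T, cytotoxic T and NK, TGF-beta signalling, IL-2 and STAT5 signalling, activation transcription factors, coinhibitory receptors, cell cycle, housekeeping, B cell, myeloid, erythroid and megakaryocyte, hepatocyte, neuron, skeletal muscle and developmental regulators of other lineages. Of their 336 genes, 335 matched a protein-coding symbol, and 20 stood in more than 1 list. A promoter counted as accessible where a region overlapped 1 kb to either side of any of the gene's start sites in both replicates. Shares were compared with all other protein-coding genes by two-sided Fisher's exact test. Replicated regions per locus, the gene body with 10 kb to either side, were compared with 100000 random lists matched on the decile of locus length in a two-sided permutation test, whose smallest possible p is 2e-05. Benjamini-Hochberg adjustment ran over the 21 lists at a threshold of 0.05. Genes are not replicates, so these tests describe the 2 libraries and not a population of mice.

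Motifs were sought on both strands within 100 bp of the summit of each of 50479 and 58876 distal regions, those with a midpoint over 1 kb from any start site. As many random windows outside regions were drawn, matched on GC content in bins of 2 percentage points. The median GC content was 47.5% in both sets, against 41.5% in unmatched windows. A motif was called where the adjusted p was under 0.05 and the ratio of shares at least 1.2 or at most 0.8 in both replicates.

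Genes were named by the fixed rule. It took 7 regulatory T cell genes, the 2 members of each other list with the most replicated regions, members of the regulatory and pan T cell lists with no promoter region, 7 cytokines, 4 lineage regulators, the 10 genes with the largest excess of regions over their length class, and the 10 strongest distal regions. Some genes that the rule takes are not reported here. Apoa1, Il1rl1, Cd3d, Cd3e, Cd247, Aurkb, Rrm2, Il5, Il9, Il24, Il17f and Il22 were named after their values were seen.

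The procedures were tested on simulated data. A planted shared fraction of 50.1% of 68832 regions was recovered as 51.1%. Among random lists of 16 genes drawn from 21911, the locus test gave an unadjusted p under 0.05 in 7.00% and the promoter test in 3.00%. Lists with counts raised 1.5 times were found in 40.5% of trials and those raised 2 times in 80.0%. Promoter lists set to 95% accessible were found in 81.0%. After an AP-1 motif was planted in some of 20000 windows, 12.7% held it, counting windows that held it beforehand. The search returned 12.7%, which checks the search for matches and not the power to call a motif. There were 0 calls among motifs that do not contain it.

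Alternatives were a -log10 q of 5 or more, the 50000 entries with the highest signal, a reciprocal overlap of 50%, -log10 q as the rank, promoters of 500 and 2500 bp, lists matched on promoter GC content, gene bodies alone or with 50 kb to either side, distal regions alone, control windows 2 kb to either side, summits with 50 bp to either side, and each replicate left out. Added after the data were seen were the 50000 entries with the highest -log10 q, the locus test without genes of more than 1 list, the locus test without the member of each list with the most regions, and the locus test against lists matched on 100 classes of locus length. Random lists kept all their members in the test without a member, which works against lists called higher. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, bedtools 2.31.1, blastn 2.17.0 and matplotlib 3.10.9.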

Results

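Chromatin accessibility was measured in mouse regulatory T cells, the Foxp3-expressing CD4 T cells that restrain immune responses. The labels give the assay as ATAC-seq, in which a transposase cuts open DNA and tags it for sequencing. The labels describe primary cells of the C57BL/6NJ strain and link a protocol for differentiating CD4 T cells, and the entry names of the deposited lists give 72 hours. Those names also hold the words ASTARR and insert, whose meaning is not given in the sources used here. Whether the lists came from plain ATAC-seq libraries or from inserts made for another assay was therefore not established, which bears on every region and signal value below. There was 1 group, with 2 libraries that the labels number as biological replicates 1 and 2. Both carry the same donor identifier, so separate animals were not established, and the spread between the libraries may be technical. Replicate 1 held 68903 accessible regions and replicate 2 held 78262, a mean of 73582.5. On chromosomes 1 to 19, X and Y, the regions covered 51.2 Mb in replicate 1 and 58.7 Mb in replicate 2, which is 1.93% and 2.22% of the ungapped genome. Median widths were 632 and 635 bp. The number of reads behind each list is unknown. With no second condition, the design allowed a comparison of the replicates with each other and a description of where accessible chromatin lay.

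The replicates shared most of their accessible chromatin. Of the 68832 regions of replicate 1 on the main chromosomes, 93.2% were overlapped by a region of replicate 2, and of the 78178 regions of replicate 2, 81.6% were overlapped by replicate 1. Lists shuffled within chromosomes gave 4.80% ± 0.09 and 4.21% ± 0.05 (SD over 20 shuffles). Regions found in both were the stronger ones and lay more often at promoters. Their median signal was 6.92 in replicate 1 and 7.17 in replicate 2, against 3.34 and 3.32 for regions found in a single replicate. Promoters made up 24.2% of the shared regions in both replicates, but 8.00% and 7.50% of the others. With replicate 1 split by signal into 10 classes of like size, 100% of the strongest class and 68.1% of the weakest were shared. In replicate 2 the share fell from 99.97% to 37.7%. The 62331 regions matched one-to-one had a Spearman correlation of signal of 0.950, a value across regions, which are not independent samples. Their summits lay a median of 19 bp apart.

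**Figure D1:**
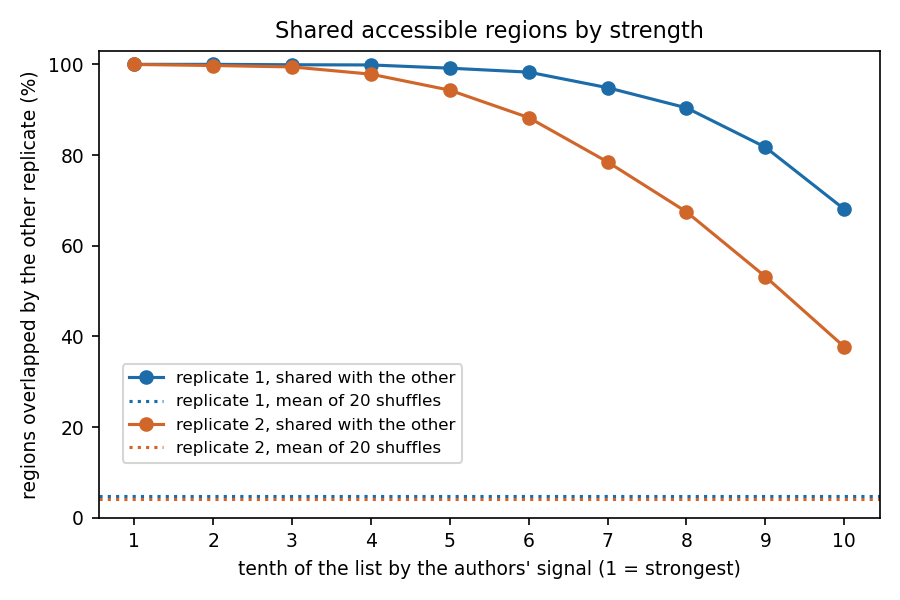
Percentage of accessible regions overlapped by the other replicate (vertical axis) for each of 10 classes of a replicate's list by signal, strongest first (horizontal axis), with dotted lines for the mean of 20 shuffled lists. In the weakest class 68.1% of regions were shared in replicate 1 and 37.7% in replicate 2, both above the shuffled 4.80% and 4.21%.

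Accessible regions were concentrated at promoters of protein-coding genes. Promoters, taken as 1 kb to either side of a start site, held 22.1% ± 1.39 of regions (SD, n = 2), 5.50 times the 4.02% of shuffled lists. Exons held 5.64% ± 0.08, or 1.41 times the shuffled share. Introns held the largest share, 42.7% ± 0.94, close to the 41.1% of shuffled lists. Intergenic DNA held 29.6% ± 0.36, against 50.9% after shuffling. Of 21911 protein-coding genes, 14208 had a promoter region in replicate 1, 14419 in replicate 2 and 14104 in both. These 14104 genes with an open promoter made up 64.4%, another 419 had a promoter region in a single replicate, and 7388 had none.

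The regulatory T cell core genes, a list of 28 surface receptors, transcription factors and mediators used to recognise this lineage, were broadly accessible. A promoter region was present in both replicates at 25 of the 28 genes (89.3%), against 64.3% of other protein-coding genes. The exceptions were Itgae and Klrg1, with no promoter region in either replicate, and Il1rl1, with a promoter region in replicate 2 alone. Itgae, which encodes the integrin CD103, still had 9 replicated regions within its locus, whereas Klrg1 had 1. Loci, taken as the gene body with 10 kb to either side, held a mean of 7.21 replicated regions across the list, 2.30 times the 3.13 of random lists matched on locus length. Per replicate the ratio was 2.19 ± 0.09 (SD, n = 2). Above the mean of their length class were 27 of the 28 genes. Two-sided Fisher's exact test gave an adjusted p of 0.0147 for promoters, and the two-sided permutation test gave 0.00972 for loci. With the lists limited to their 50000 strongest entries by signal, 75.0% of all 28 promoters were accessible and Fisher's exact test no longer passed (adjusted p = 0.184). Lists of the same length by -log10 q were an alternative chosen after the data were seen. With them 89.3% of all 28 promoters were accessible, as with the full lists, and the call by Fisher's exact test stayed (adjusted p = 0.0051).

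Among single genes, Il2ra, which encodes the high-affinity chain of the interleukin-2 receptor, had the most replicated regions of this list. Its locus held 19 regions in replicate 1 and 21 in replicate 2, of which 18 were replicated, 5.04 times the mean for its length class. These regions were weak by signal, with a median at the 0.94 percentile in replicate 1 and 1.03 in replicate 2, and at 32.0 and 31.9 by -log10 q. With lists of 50000 entries, 2 replicated regions were left by signal and 11 by -log10 q. Ctla4, an inhibitory receptor that competes for CD28 ligands, had 10 replicated regions (3.37 times). The Ikaros family genes Ikzf2 (Helios) and Ikzf4 (Eos) had 14 and 6, or 1.87 and 2.49 times the mean for their length class. Icos, a costimulatory receptor beside Ctla4 on chromosome 1, had 6 (2.27 times). Tnfrsf18, which encodes the receptor GITR, had 4 (3.58 times, or 2.49 times with 100 classes of length). Its promoter region was weak by signal, at the 1.44 and 3.04 percentile in replicates 1 and 2. In lists of 50000 entries Tnfrsf18 kept 1 replicated region by signal and 3 by -log10 q. All 7 genes named here and next, Foxp3 included, had promoter regions in both replicates.

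Foxp3, the lineage-defining transcription factor, lies at X:7573644-7595245 on the plus strand (mm10). Its locus held 9 regions in replicate 1 and 8 in replicate 2, and each was overlapped by the other replicate. The main transcript starts at 7579676 and has 14 exons. A region at 7578769-7579440 in replicate 1 had its summit at -0.765 kb from that start. A region at 7583899-7584907 lay in the first intron, with its summit at 4.663 kb in both replicates. A region at 7593438-7594411 lay in exon 14, the 3′ exon, which overlaps the end of Ccdc22 on the opposite strand. No region was called in the introns between exon 2 and exon 14. Upstream, a region at 7573807-7575183 in replicate 1 lay inside the annotated Foxp3 gene model and at the start of Ppp1r3f, with its summit at -5.145 kb in both replicates. In replicate 2 the same stretch and a smaller neighbour formed a single region, 7572650-7575182. Another region at 7566454-7568104 lay within Ppp1r3f. By signal the strongest region, with 12.8 in replicate 1 and 14.3 in replicate 2, lay at 7604963-7605783, at the start of Ccdc22, so it need not belong to Foxp3. By -log10 q the region at -5.145 kb came first, with 105 and 198, against 51.0 and 100 for the region at Ccdc22. The first intron region had a signal of 6.34 and 5.39, at the 47.9 and 43.6 percentile of its list, and stood at 78.9 and 75.7 by -log10 q.

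**Figure D2:**
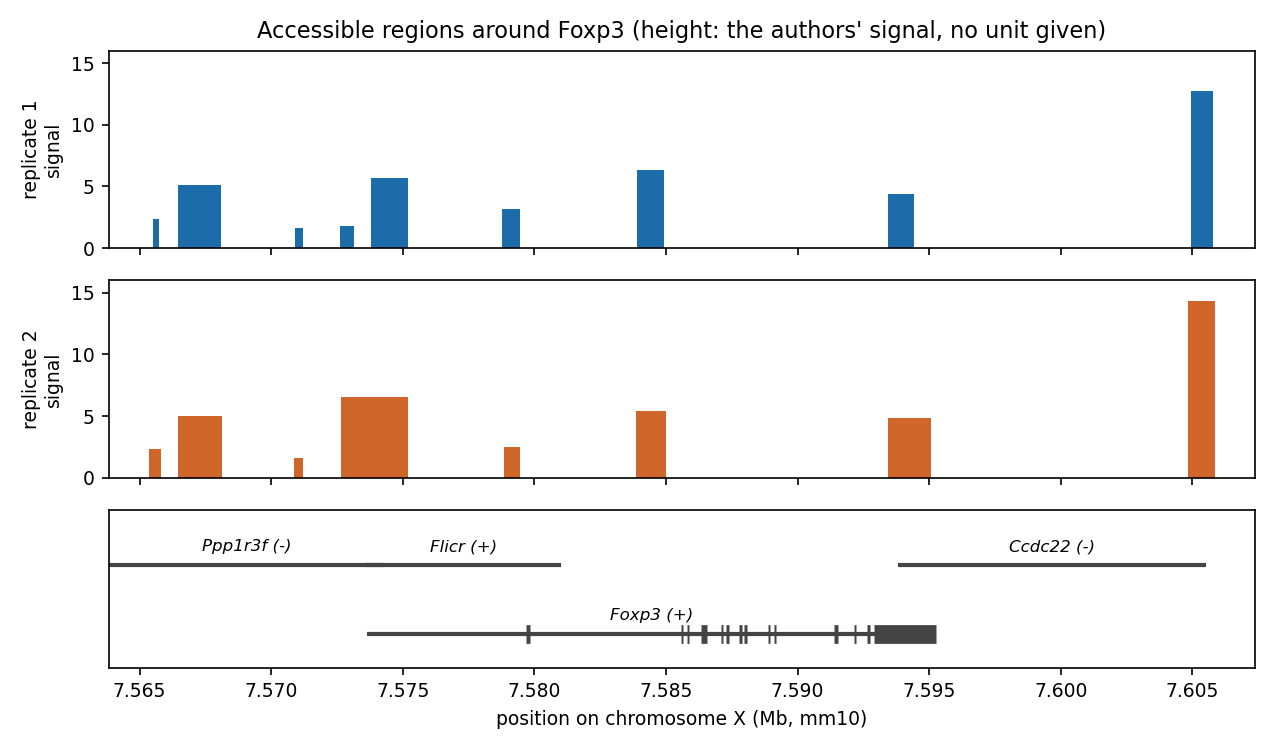
Accessible regions around Foxp3, with position on chromosome X in Mb of mm10 (horizontal axis) and the authors' signal as bar height for each replicate (upper panels), above gene bodies and the 14 exons of the main Foxp3 transcript (lower panel). The 9 regions of replicate 1 and the 8 of replicate 2 lie at the same places, and the highest bar, 12.8 and 14.3, stands at the start of Ccdc22.

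T cell identity and signalling genes carried more regions than random lists matched on the decile of locus length. Random lists were drawn from all protein-coding genes, and the housekeeping list also passed, at 1.88. A raised ratio is therefore not particular to T cell genes. The longest decile spans a wide range of lengths. Matched on 100 classes of length, an alternative chosen after the data were seen, the same 12 lists passed as higher, with a ratio of 3.33 for naive and quiescent T cell genes and 2.35 for T helper 17 genes. The last of these classes still ran from 513 to 4435 kb and held Foxp1 and Rora. All 27 pan T cell genes, such as the receptor chains Cd3d, Cd3e and Cd247, had promoter regions in both replicates (adjusted p = 8.55e-05, Fisher's exact test). Their loci held 2.73 times the regions of matched random lists (adjusted p = 0.0121, permutation test), with 28 replicated regions at Ets1 and 26 at Runx1, transcription factors of T cell development. Naive and quiescent T cell genes had the highest ratio, 3.56 (adjusted p = 0.00972, permutation test), in which Foxp1 with 65 regions and Bach2 with 51 made up more than the other 13 members. Of their promoters, 14 of 15 were accessible, short of the threshold (adjusted p = 0.0511, Fisher's exact test), though they passed in 3 of 8 alternatives, among them a -log10 q of 5 or more (adjusted p = 0.0292, Fisher's exact test). Activation transcription factors followed at 3.15, and all 24 had accessible promoters. Bach2, which stands in this list too, held 51 of their 212 regions, and Nfkb1 23. Without the member with the most regions, a check chosen after the data were seen, the ratio was 2.82 for naive and quiescent T cell genes and 2.69 for activation transcription factors, and both passed the permutation test (adjusted p = 0.012 and 0.00913). Genes of IL-2 and STAT5 signalling, the growth factor pathway on which regulatory T cells depend, reached 2.82. The survival gene Bcl2 held 26 of their regions, and the kinase gene Jak1 and Il2ra held 18 each. All 18 of these promoters were accessible (adjusted p = 0.00286, Fisher's exact test). Genes of TGF-beta signalling, the cytokine that induces Foxp3 in culture, reached 2.17, with 26 regions at Ldlrad4 and 20 at Tgfbr3, and 16 of 17 promoters were accessible (adjusted p = 0.0246, Fisher's exact test). Coinhibitory receptors reached 1.90, with 10 regions at Ctla4 and 8 at Entpd1 (1.07 times the mean for its length class), which encodes the ectonucleotidase CD39, and 11 of 12 promoters were accessible (adjusted p = 0.108, Fisher's exact test), and all 12 in replicate 1 alone (adjusted p = 0.0237, Fisher's exact test). In a permutation test against lists matched on promoter GC content, the promoter calls ended for TGF-beta signalling (adjusted p = 0.338) and activation transcription factors (adjusted p = 0.0899). With the 50000 strongest entries by signal, the promoter calls by Fisher's exact test ended for IL-2 and STAT5 signalling (adjusted p = 0.11) and TGF-beta signalling (adjusted p = 0.141), and the locus call for coinhibitory receptors (adjusted p = 0.124, permutation test). With the 50000 strongest entries by -log10 q these calls stayed, with an adjusted p of 0.0068 for both promoter lists (Fisher's exact test) and 0.0125 for coinhibitory loci (permutation test).

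**Figure D3:**
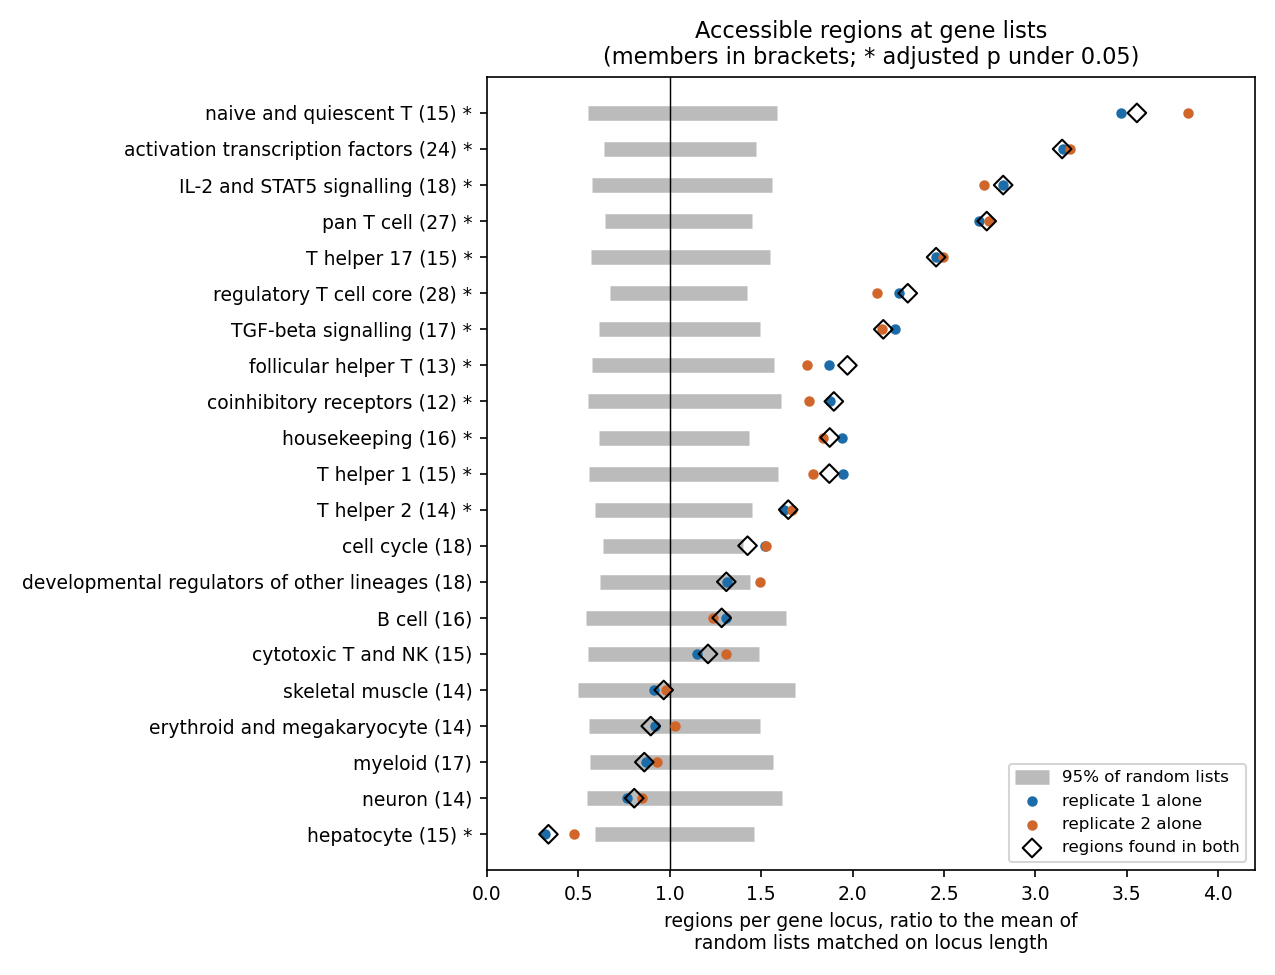
Accessible regions per gene locus for each of 21 gene lists, as the ratio to random lists matched on locus length (horizontal axis). Diamonds show regions found in both replicates, points show each replicate alone, and bars span 95% of random lists. The ratio was highest for naive and quiescent T cell genes (3.56) and lowest for hepatocyte genes (0.34).

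Genes of the other CD4 T helper lineages were also accessible, and no comparison with those lineages was possible here. The same test gave 1.88 for housekeeping loci, which the T helper 1 and T helper 2 ratios did not exceed and the follicular helper ratio barely did. Loci of T helper 17 genes held 2.46 times the regions of random lists, with 8 regions at Ccr6 and 49 of the 108 at Rora, and 1.62 times without Rora (adjusted p = 0.0278, permutation test). The ratio was 1.97 for follicular helper T genes (17 regions at Il6ra and 9 at Cxcr5), 1.87 for T helper 1 genes (18 at Stat4 and 10 at Il12rb2) and 1.65 for T helper 2 genes (7 at Il4ra and 6 at Gata3). These 4 lists passed the permutation test, with adjusted p from 0.00972 to 0.0214. Their promoters did not pass Fisher's exact test: 14 of 15 T helper 1 promoters (adjusted p = 0.0511), 12 of 15 T helper 17, 11 of 13 follicular helper and 10 of 14 T helper 2 promoters were accessible. The T helper 1 promoters passed in 5 of 8 alternatives: matched on promoter GC content (adjusted p = 6.3e-04, permutation test), and by Fisher's exact test at a -log10 q of 5 or more (adjusted p = 0.0292), with the 50000 strongest entries by signal (0.0284) or by -log10 q (0.0165), and in replicate 1 alone (0.00601). The locus calls of the permutation test for T helper 2 and follicular helper T genes ended with only the 50000 strongest entries by signal (adjusted p = 0.0762 and 0.103) and without genes of more than 1 list (adjusted p = 0.13 and 0.0569), and the T helper 2 call also with 50 kb to either side (adjusted p = 0.0808). The follicular helper call also ended without Il6ra, its member with the most regions (adjusted p = 0.0593, permutation test). Both calls stayed with the 50000 strongest entries by -log10 q (adjusted p = 0.01 for each, permutation test).

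Signature cytokines differed in their promoters. Ifng, Il10 and Il2 had promoter regions in both replicates, Il4 in replicate 2 alone, and Il13, Il17a and Il21 in neither. The T helper 2 and T helper 17 lists hold further interleukin genes. Of these, Il5, Il9, Il24 and Il17f had promoter regions in both replicates and Il22 in neither. The Il2 promoter region was weak, at the 4.06 and 7.56 percentile of signal in replicates 1 and 2. The Il10 region, of the suppressive cytokine IL-10, stood at the 30.1 and 20.2 percentile and the Ifng region at the 39.6 and 48.0 percentile. Il13, Il10, Il4 and Il2 loci each had 3 replicated regions, Il21 had 4, and Il17a and Ifng had 2. The lineage regulators Gata3, Tbx21 and Bcl6 had promoter regions in both replicates. By signal, Gata3 stood highest of these, at the 89.1 and 86.2 percentile, followed by Tbx21 (35.5 and 51.2) and Bcl6 (10.4 and 29.9). The measure matters for their loci. With lists of 50000 entries, Bcl6 kept 2 replicated regions by signal and 6 by -log10 q, Tbx21 2 and 3, and Gata3 3 and 5.

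Cell cycle and housekeeping genes were accessible at every promoter tested, 18 of 18 and 16 of 16 (adjusted p = 0.00286 and 0.00391, Fisher's exact test). The housekeeping promoter call was lost in a permutation test against lists matched on GC content (adjusted p = 0.075) and in Fisher's exact test with the 50000 strongest entries by signal (adjusted p = 0.0689). Its locus call was lost in the permutation test with those entries (adjusted p = 0.0762) and for gene bodies alone (adjusted p = 0.0509). With the 50000 strongest entries by -log10 q the housekeeping list passed at promoters (adjusted p = 0.00171, Fisher's exact test) and at loci (adjusted p = 0.01, permutation test). By signal, the promoter region of Aurka stood at the 93.5 and 96.4 percentile of its list, Top2a at 87.2 and 90.1, Rrm2 at 54.1 and 58.2 and Aurkb at 47.5 and 52.7, and no test was run on these values. Loci of housekeeping genes held 1.88 times the regions of random lists (adjusted p = 0.00252, permutation test), with 8 at Ywhaz and 6 at Actb. Loci of cell cycle genes held 1.43 times and did not pass (adjusted p = 0.0605, permutation test), although they passed in each replicate alone and with 50 kb to either side (adjusted p = 0.0147, permutation test).

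Among markers of other cell types, 2 lists passed as less accessible at promoters and 1 at loci. Hepatocyte genes were the least accessible, with a promoter region at 1 of 15 genes, the apolipoprotein gene Apoa1 (adjusted p = 8.55e-05, Fisher's exact test). Their loci held 0.34 times the regions of random lists (adjusted p = 0.00972, permutation test). Apoa2 had 3 replicated regions. The locus call of the permutation test ended for distal regions alone (adjusted p = 0.164) and with 50 kb to either side (adjusted p = 0.061). Myeloid promoters were accessible at 6 of 17 genes (adjusted p = 0.046, Fisher's exact test), a call that ended in 5 of 8 alternatives, among them replicate 2 and replicate 1 alone (adjusted p = 0.071 and 0.115), and their loci were near the random mean at 0.86. Mrc1 held 5 regions there (0.98 times the mean for its length class) and Cebpb 4 (3.58 times). The other lists did not pass at promoters or loci as tested in both replicates. Accessible promoters numbered 7 of 15 for cytotoxic T and NK genes, 9 of 16 for B cell, 6 of 14 for erythroid and megakaryocyte, 9 of 14 for neuron, 5 of 14 for skeletal muscle and 13 of 18 for developmental regulators of other lineages. Skeletal muscle promoters passed as lower against lists matched on GC content (adjusted p = 0.0115, permutation test) and with promoters of 500 bp (adjusted p = 0.0232, Fisher's exact test). Developmental regulators passed as higher in replicate 2 alone, at promoters (adjusted p = 0.0245, Fisher's exact test) and at loci (adjusted p = 0.0342, permutation test). The developmental promoters went the other way with the 50000 strongest entries, to 44.4% by signal and 33.3% by -log10 q, from 72.2% as reported (adjusted p = 0.305 and 0.0543, Fisher's exact test). Their locus ratio fell below 1 with both, to 0.96 and 0.92, so this list had no stable direction. Locus ratios were 1.21, 1.28, 0.90, 0.81, 0.97 and 1.31 in the same order. For B cell, cytotoxic and neuron genes the median member lay on the other side of its length class from the mean. The members with the most regions follow, with the ratio to the mean for their length class. Among B cell genes these were Ebf1 with 19 (2.53) and Pax5 with 7 (0.93), level with Bank1 at 7 (0.93). Among cytotoxic genes they were Gzmk with 7 (1.96) and Eomes with 5 (3.05), and among erythroid genes Tal1 with 6 (2.49) and Klf1 with 4 (2.51). Gad1 with 7 (1.96) and Gad2 with 6 (1.18) led the neuron list, Ryr1 with 9 (1.2) and Ckm with 6 (2.27) the muscle list, and Lhx2 with 8 (2.69) and Gata4 with 7 (1.38) the developmental list.

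Most of the motifs tested were more frequent in distal regions than in GC-matched windows. The CTCF consensus occurred at 5.79% ± 0.18 of summits (SD, n = 2) against 0.08% ± 0.03 of GC-matched windows, a ratio of 75.9 ± 28.8. The spread of this ratio comes mostly from the random control windows, of which 31 held a match for replicate 1 and 60 for replicate 2. The share of regions was alike, at 5.91% and 5.66%. The AP-1 consensus, bound by Fos, Jun and BATF, was the most frequent of the 26 tested, at 18.8% ± 0.66 against 3.21%, a ratio of 5.86 ± 0.21. Composite sites of AP-1 with IRF and of AP-1 with NFAT had ratios of 14.7 ± 0.17 and 11.4 ± 3.64, at 0.46% and 0.12% of regions. Few control windows held these composites, 15 and 19 for IRF and 7 and 5 for NFAT in replicates 1 and 2, so the size of these ratios is uncertain. ETS stood at 7.02 ± 0.25, NF-kB at 5.28 ± 0.29, STAT5 at 3.81 ± 0.06, RUNX at 3.62 ± 0.02, NR4A at 3.20 ± 0.29 and SMAD at 3.15 ± 0.14. In all, 20 motifs were called higher in both replicates by two-sided Fisher's exact test, with a highest adjusted p of 0.00845, for MYC. Regions are not independent samples and the replicates share most of them, so these tests describe the 2 libraries. The MYC call ended with the 50000 strongest entries by signal (adjusted p = 0.0938) and with 50 bp to either side of the summit (adjusted p = 0.273), both by Fisher's exact test, and stayed with the 50000 by -log10 q. The others called were the second AP-1 and IRF form (14.4), PU.1 (4.45), ETS-RUNX (2.77), MEF2 (2.76), ISRE (2.03), ROR (1.86), KLF-SP (1.68), TCF-LEF (1.61) and the E-box (1.29), with MYC at 1.39. Of these, the first 3 also rest on few control matches, from 7 to 29 per replicate. MEF2 had been set as a factor of other tissues. The forkhead consensus, the site of the protein family to which Foxp3 belongs, occurred at 2.37% ± 0.02 of regions against 2.33% ± 0.03, a ratio of 1.02 ± 0.02, and was not called (adjusted p = 1 by Fisher's exact test). Against control windows 2 kb to either side its ratio was 0.82 (adjusted p = 4.41e-09 by Fisher's exact test), short of the limit of 0.8 for a call. Those windows were not matched on GC content, so a difference in GC content can enter this ratio. GATA (1.06), NFAT alone (1.02), T-box (1.01) and HNF4 (0.83) were not called either. TEAD was lower, at 0.68 ± 0.01 of the share in control windows (adjusted p = 7.0e-15, Fisher's exact test). These are matches to a consensus and do not identify which protein of a family was bound.

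**Figure D4:**
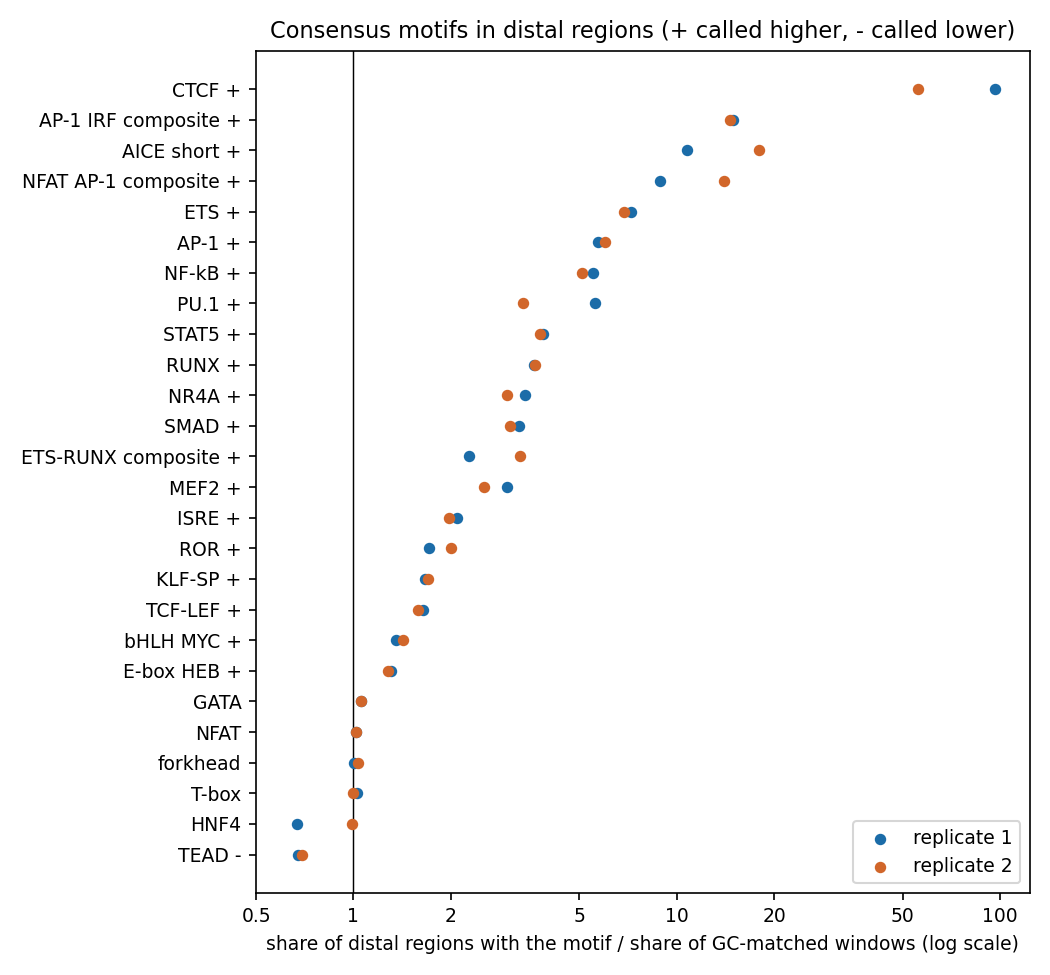
Ratio of the share of distal regions with a consensus motif to the share of GC-matched windows, on a log scale (horizontal axis), for 26 motifs in each replicate (points). CTCF stands highest (mean ratio 75.9), AP-1 at 5.86, forkhead at 1.02 and TEAD lowest at 0.68.

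Protein-coding genes with the largest excess of replicated regions over their length class were long ones, since the longest class spans a wide range of lengths with a mean of 7.50 regions. Foxp1 had 65, Inpp4b 58, Pde4d 52, Bach2 51, Rora 49 and Hivep3 39. The highest counts belonged to gene models that span others: Gm20388, with 296 regions over 4435 kb that hold 71 other genes, and Fgfr2, with 109 over 2961 kb that hold 29. Gm37240 (49) holds 6 other genes, and Gm20696 (45), which overlaps Foxp1, and Hivep3 hold 1 each. Per 100 kb of locus, the gene body with 10 kb to either side, Bach2 had 13.9 regions and Foxp1 10.5, while Il2ra had 25.6 and Foxp3 21.6. The gene bodies of the former are 347 and 597 kb long and those of the latter 50.4 and 21.6 kb. These densities therefore come from loci of unlike length. Actb had 25.4 and Il6ra 24.6, so values of this size are not particular to regulatory T cell genes.

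Of the 10 strongest replicated distal regions, 9 had nearly the same boundaries in both replicates, and the region on chromosome 17 started at 22877402 in replicate 1 and at 22876315 in replicate 2. The strongest, 1:100180106-100180425 (mm10), lay in an intron of Cntnap5b, 72363 bp from the nearest start of a protein-coding gene, with a signal of 38.2 and 38.9. Next were 9:123461798-123462187 in an exon of Lars2 (36.3 and 36.5) and 12:78350869-78351176 in an intron of Gphn (32.7 and 33.8). Intergenic regions followed at 3:62159051-62159489, 3:5860341-5860819, 17:22877402-22878163 and 18:85697948-85698278, with nearest starts at Arhgef26, Gm8797, Zfp945 and Neto1. The remaining 3 lay at 2:5378732-5379374 within Camk1d, 7:130834363-130834641 within the long Fgfr2 gene model and 13:44869571-44870061 within Jarid2. Their nearest starts were at Ccdc3, at Plekha1 (31254 bp away) and at Jarid2. Regions known for high signal from repeats could not be removed. Of these 10, 8 had at least 1 other copy in the genome, against 8 of 200 random replicated distal regions, so their signal need not reflect open chromatin at these places.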

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

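The tests in this part of signal in dense loci, of the list limits, of reads behind replicate 2 and of regions with any other copy were chosen after the result was seen, and the others before.

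Regions on scaffolds outside the main chromosomes and the mitochondrial genome, which no comparison used, numbered 69 in replicate 1 and 82 in replicate 2. They are given here because they lie outside the comparisons and are more than the 3 that a count of 0 allows, which any list of some length passes, so whether these numbers are unusual was not tested. The scaffold JH584304 held 21 of them in replicate 1 and 25 in replicate 2.

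Regions in crowded loci ranked lower by signal than by -log10 q, and the densest of them had a median percentile of 37.6 and 38.2 by signal and 55.1 and 54.6 by -log10 q. Regions at regulatory T cell core loci had a median signal percentile of 36.0 in replicate 1 and 37.9 in replicate 2, but a median -log10 q percentile of 64.1 and 62.9. The latter argues against weakly called regions at these loci taken as a set, but the median -log10 q percentile was 32.0 and 31.9 at Il2ra and 37.4 and 33.2 at Ikzf2, where weak calls stay open. A signal scaled to local coverage stays open: signal fell against -log10 q as neighbours within 50 kb became more numerous, with a Spearman correlation across regions of -0.44 at the weaker of the replicates, but this restates the pattern and does not test its source. No biological explanation was tested, and which scale the signal has stays open.

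Replicate 2 held more regions, and 97.6% of the regions it alone held were in the weaker portion of its list by -log10 q. The lowest -log10 q of the lists differed by 6.0e-04, which argues against a weaker limit in replicate 2. Among 19284 matched regions with signal within 5%, 99.9% had the higher -log10 q in replicate 2, by a median ratio of 1.46, so more reads behind replicate 2 may account for the longer list. Cells of other types stay open: 19.5% of 200 regions at B cell, myeloid, erythroid and cytotoxic loci (95% exact interval 14.2 to 25.7%) were in replicate 2 alone, against 18.4% elsewhere, and the interval spans the 22.0% set as the limit. The design gives no groups, so no biological explanation was tested.

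The 10 strongest distal regions were tested for 2 technical sources. None aligned to the mitochondrial genome over 100 bp (0 of 10), which argues against mitochondrial sequence. Sequence present in many copies of the genome stays open, since the counts are few: 2 of the 10 aligned to 10 or more other places, as did 2 of 200 random replicated distal regions, while 8 of the 10 and 8 of the 200 had at least 1 other copy. No biological explanation was tested.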

How the results depend on the processing

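The lists of 50000 entries by -log10 q and the locus tests without genes of more than 1 list, without each list's member with the most regions and with 100 classes of length were chosen after the results were seen, and the other alternatives before. No paired analysis was possible because the series has 1 group. No call reversed, but 29 values of 13 results with no call changed direction, most often for developmental regulators. The number of accessible regions, regions shared between replicates, rank agreement of peak strength, genomic distribution of regions, promoter accessibility of gene lists, regions per locus of gene lists and motifs in distal regions moved as follows, and where the construction does not show it, the cause was not tested. A -log10 q of 5 or more left a mean of 64369.5 regions, with 96.2% and 83.2% shared, a rank correlation of 0.947, 23.8% at promoters and 9 promoter lists higher (7 as reported). The 50000 strongest by signal gave 91.3% and 91.2% shared, 0.927 and 27.1%, with 4 promoter lists higher and 1 lower (2 as reported), and 8 locus lists higher (12 as reported). The 50000 by -log10 q gave 92.4% and 92.0%, 0.945 and 27.9%, with 8 promoter lists higher and 1 lower. Reciprocal overlap of 50% gave 86.3% and 75.9%. Ranking by -log10 q gave 0.965. Promoters of 500 bp held 19.2%, with 3 lists lower, and those of 2500 bp 28.4%, with 1 lower and, as with 500 bp, 8 higher. Matching on GC content gave 5 higher and 3 lower. Loci with 50 kb to either side and distal regions alone gave 0 lists lower. Control windows 2 kb away, which were not matched on GC content, and summits with 50 bp to either side gave 2 motifs lower, HNF4 joining TEAD. With each replicate left out, 1 promoter list (1 to 1) and 1 to 2 motifs were lower. Among single lists and motifs, 26 values lost their call and 19 gained one, 10 of the losses with the 50000 strongest by signal and 1 with the 50000 by -log10 q. The NFAT and AP-1 composite lost its call at 50 bp because the control windows of a replicate held no match. The unknown depth limits what a missing region shows.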

Other observations

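These values, apart from the promoter shares by GC content, were chosen after the data were seen, and no test was run on them.

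Regions were unevenly spread. Of 27268 windows of 100 kb, 51.5% held no replicated region, and 1359 held 10 or more. The densest window, 2:11600001-11700000, held 24 and contains Il2ra and Rbm17. The next, 14:66200001-66300000, held 22 and contains Ptk2b and Trim35. Windows with 20 or 21 contained, among others, Cd69, an early activation marker, Ets1, Prkch and Cytip, a cluster of histone genes on chromosome 13, the retinoic acid receptor gene Rara beside Top2a, Pip4k2a and Igf1r. A window at 8:126800001-126900000 with 20 regions contained no protein-coding gene.

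Chromosomes differed in density. The median autosome held 27.7 regions per Mb in replicate 1 and 31.2 in replicate 2, with chromosome 14 lowest (21.5 and 24.5) and chromosome 11 highest (42.1 and 47.8). Chromosome X held 9.46 and 10.7, and Y held 0.14 and 0.19. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had promoter regions in both replicates, with Uty at the 83.7 and 83.8 percentile of signal, while Zfy1 and Zfy2 had none. Xist, the RNA of the inactive X chromosome, also had a promoter region in both replicates, at the 42.8 and 46.8 percentile. The labels give no sex for these mice.

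The mitochondrial genome held 2 long regions in each replicate, at 136-4782 and 10883-16084 in replicate 1 and at 131-4781 and 10861-16101 in replicate 2, with none between them.

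Promoter accessibility rose with GC content. Of protein-coding genes in the lowest of 5 classes of promoter GC, 17.1% had an accessible promoter in both replicates, and in the highest 88.8%.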
